A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

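RNA from shoots and roots of rice seedlings was measured on 12 arrays, 1 per sample, of a 1-colour Agilent rice design with 45151 spots. The samples form 4 groups of 3, shoot -P, shoot -P/-N, root -P and root -P/-N. According to the file headers, the authors scanned the arrays and used Agilent Feature Extraction 11.5.1.1, which detrends and subtracts the background within each array and gives a processed signal. The deposited scanner files hold intensity values per spot, per the file headers, with no scaling between arrays. The deposited series table holds log2 values, which the authors made from the processed signal by subtracting a constant per array, found here to equal the 75th percentile over all spots. The scanner values were used, and the series table served as an alternative.

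Spots that are scanner controls (1417) or other controls (590) were left out, which leaves 43144 spots. Spots called non-uniform by the scanner software were left out, and 60 probes with no other spot on some array were dropped, which leaves 42358 probes. No spot was saturated. Values were log2 of the processed signal less the array's 75th percentile over non-control probes, averaged over spots of 1 probe. Each gene was represented by its brightest probe, the one with the highest mean over the 12 arrays. This gave 29661 loci and 510 items for microRNA precursors without a locus, and 7780 loci had more than 1 probe. A gene was tested in a tissue if it was well above background, by the scanner software's own call, on all 3 arrays of at least 1 of the 2 groups, and for the interaction if it passed in both tissues.

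Changes were tested with limma 3.58.1 in R 4.3.3, as 1 model of 4 group means over all 12 arrays with moderated variances (8 residual degrees of freedom). Each gene had 1 variance for both tissues, so its SE in 1 tissue also reflects the spread in the other. Adjusted p-values are those of Benjamini and Hochberg, with a threshold of 0.05, and the SE is that of the moderated fit. The median SE over genes was 0.0988 in shoot and 0.103 in root on the log2 scale. The contrasts were -P/-N against -P in each tissue and the difference of the 2 responses. For groups not well above background, fold changes are given relative to a floor. This floor is the array's lowest value among probes called well above background, or the measured value where that is higher. Other probes with values above the floor were also not called, so these fold changes are approximate and not strict lower bounds. Slides were read from the files, and fits with the slide as a block and within the slide that holds both groups stand beside each count. Both rest on 1 -P array per tissue. The comparison of genes changed in both tissues used the expected overlap of independent lists and Fisher's exact test.

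Gene lists were 13 curated and 21 chosen by words in the gene descriptions, fixed before the data were examined. A list was tested with 4 or more measured genes by camera with a preset correlation of 0.01, again with the correlation estimated per list and by fry, and its members also adjusted over the list alone. Of 146 curated loci 140 were on the array. For 123 the description in the array file matched the name, for 17 it was uninformative or different and the name rests on the locus, and 0 were dropped. These 17 include NRT2.1, NAR2.1, NRT1.1C, PHO1;1 and NPF7.2. Near-identical copies (NRT2.1 and NRT2.2, NIA1 and NIA2, NAS1 and NAS2, RR9 and RR10, PT1 and PT2) may share signal. The naming rule fixed beforehand was 14 sentinel genes whatever their result, the 8 largest rises and falls per tissue among genes changed at least 2-fold with no overlap between the groups' arrays and an informative description, the 4 genes with the lowest adjusted p per list, and the 5 genes with the most positive and most negative interaction among those with a description. Not every gene the rule covers is named in the text.

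The alternatives tried were normexp background correction (offset 50), quantile or median scaling or none, the authors' log2 values, filters on dim probes, the slide as a fixed or random block, replicate number as a block, the 6 arrays of a tissue alone, the mean of all probes or every probe, array weights, an intensity trend, and each array left out in turn. The pipeline was tested on simulated data, with each gene's mean in its tissue, normal noise of that gene's residual SD, independent between genes, and known changes added. It recovered 55.2%, 85.1% and 95.5% of changes of 0.5, 1 and 2 on the log2 scale in shoot, 58.2%, 89.6% and 98.5% in root, and 35.4%, 78.4% and 93.2% in the interaction, with 15, 12 and 13 unchanged genes called and 0 calls where no change was made. A list shifted by -0.5 was called in both tissues, and 0 other lists were. Since the simulated noise was independent between genes, this does not show how often camera calls lists of correlated genes. With the real arrays of a tissue split in other ways, 2 to 9 lists were called in shoot and 3 to 13 in root. Sequences and genome coordinates of the probes were not used here, since no genome was given. Figures were drawn with matplotlib 3.10.9.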

Results

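Transcript levels were measured in shoots and roots of young seedlings of the japonica rice cultivar Nipponbare. The plants had spent 5 days in a nutrient solution without phosphate and were then kept either without phosphate alone (-P) or without phosphate and without ammonium nitrate, the nitrogen source (-P/-N), for 6 h before harvest. The comparison asks how the removal of nitrogen changes transcript levels in plants that are already short of phosphate. There were 12 arrays of 1 colour in 4 groups of 3, shoot -P, shoot -P/-N, root -P and root -P/-N. Between 76.4% and 79.2% of the probes were well above background on the shoot arrays, and between 80.3% and 81.9% on the root arrays. The number of arrays limits the precision. The labels number the replicates but do not say that they were separate plants or cultures, so the p-values measure the spread between these samples, which may be technical.

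The marker genes placed every array in the tissue its label gives. All 8 photosynthesis markers were higher on every shoot array than on every root array, for example RbcS2, a small subunit of Rubisco, by 8.66 on the log2 scale. All 4 root markers were higher on every root array, and RCc3 and the silicon exporter Lsi2 were not well above background on any of the 6 shoot arrays. In each tissue the 3 -P/-N arrays and -P replicate 1 shared a slide, while -P replicates 2 and 3 lay on another slide. Counts and list tests are therefore given also with the slide as a block and within the slide that holds both groups. Both of these checks compare -P replicate 1 alone with the 3 -P/-N arrays and give the same estimate, with different errors, so they are not 2 separate lines of evidence. The shoot and root arrays lay on different slides scanned on different days, so differences in level between shoot and root far smaller than those of the markers cannot be told apart from the slide. A slide term in the fit passed for 1 gene in shoot and 0 in root, and had an unadjusted p under 0.05 for 2899 of 22275 and 639 of 23602 genes, where 5% would by chance.

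In root, the removal of nitrogen raised the genes of high-affinity nitrate uptake. NRT2.1, a root nitrate transporter, was not well above background on any -P array and was 471-fold above the floor in -P/-N (adjusted p = 2.38e-10, with the slide block 4.46e-07). NRT2.2 rose by 2.58 ± 0.13 on the log2 scale (SE of the fit, n = 3 per group), a 5.96-fold rise (adjusted p = 9.01e-06). NRT2.3 rose by 2.35 ± 0.30 (adjusted p = 0.00207), and NAR2.1, the partner protein that NRT2 transporters need, rose by 1.82 ± 0.23 (adjusted p = 0.0018). NRT2.1 and NRT2.2 are near-identical copies, so their probes may share signal. On the 3 -P arrays the NRT2.2 probe was at log2 levels of 0.285 to 0.586, while the NRT2.1 probe was not well above background. The NRT2.1 probe thus did not respond to what the NRT2.2 probe measured there. Whether the NRT2.2 probe also responds to NRT2.1 is uncertain. Of the 11 tested genes of the nitrate transport list, 5 rose, 0 fell and 6 did not pass the test (6 rose when adjusted over the list alone). The list as a whole was shifted up, with a median log2 change of 0.39 (camera adjusted p = 6.5e-10, but adjusted p = 0.0887 with an estimated correlation). With the slide as a block the list's adjusted p was 3.07e-09, and within the shared slide its median was 0.41 (adjusted p = 5.46e-09). NRT2.1 and NRT2.2 kept their calls with the block, while NRT2.3 (adjusted p = 0.0778) and NAR2.1 (adjusted p = 0.105) did not, with blocked log2 changes of 2.41 and 1.65.

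Ammonium and urea transporters of the root moved both ways. AMT1;2, an ammonium transporter of the root, rose by 3.01 ± 0.18, an 8.04-fold rise (adjusted p = 3.51e-05). The urea transporter DUR3 rose by 1.99 ± 0.18 (adjusted p = 0.000264) and AMT3;3 by 1.31 ± 0.14 (adjusted p = 0.000584). AMT2;3 fell by 1.66 ± 0.20 (adjusted p = 0.00159, with the slide block 0.0912), and AMT1;3 and AMT2;2 fell by 0.69 and 0.65. Of 10 tested genes of this list, 3 rose, 3 fell and 4 did not pass (6 rose and 3 fell when adjusted over the list alone). The list was shifted up (median 0.39, camera adjusted p = 0.0246, adjusted p = 0.435 with an estimated correlation, 0.00997 with the slide block and 0.00716 within the shared slide). All 3 rises and 0 of the 3 falls kept their calls with the block.

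**Figure D1:**
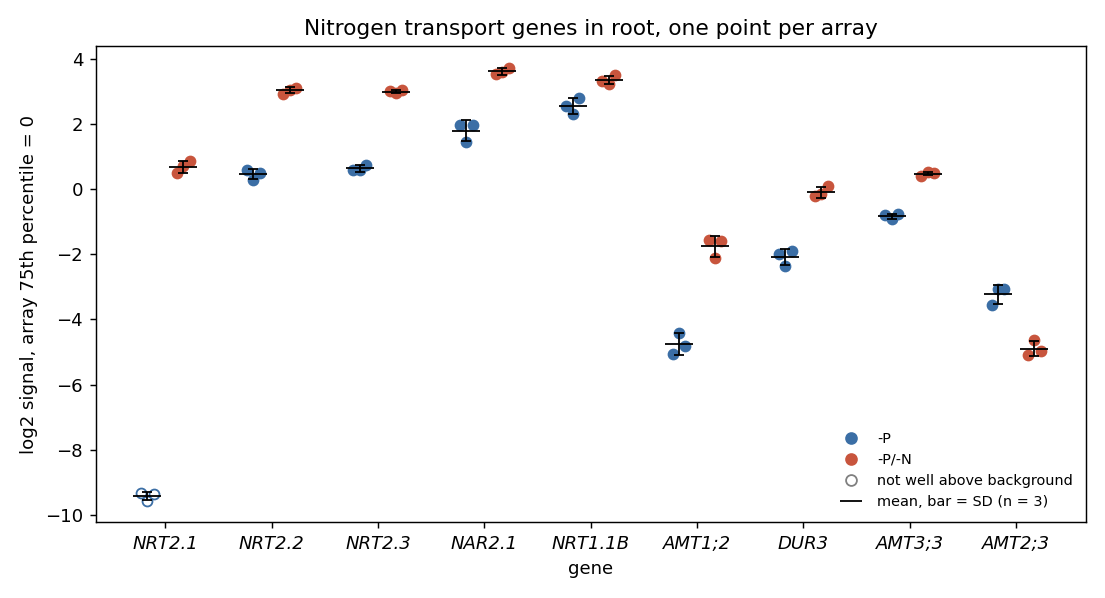
Levels of 9 nitrogen transport genes on the 6 root arrays, as log2 signal relative to each array's 75th percentile, with 1 point per array, the mean and the SD (n = 3). NRT2.1 was not well above background on the 3 -P arrays (open points) and was the gene with the widest gap between the groups, while AMT2;3 was lower in -P/-N.

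Genes of nitrogen assimilation in root fell or did not pass the test, with 1 exception. NADH-GOGAT1, a glutamate synthase, fell by 0.90 ± 0.08 (adjusted p = 0.00017) and GS1;2, a cytosolic glutamine synthetase, fell by 0.74 ± 0.11 (adjusted p = 0.0047). The glutamate dehydrogenases GDH1 and GDH2 fell by 0.33 and 0.41, and the asparagine synthetase ASN2 rose by 0.55 ± 0.09 (adjusted p = 0.00573). ASN1 had a log2 change of -2.94 ± 0.86 that did not pass the test (adjusted p = 0.0896). Its spread was small on the root arrays (SD 0.05 in -P and 0.07 in -P/-N) and large on the shoot arrays (0.79 and 2.21). The SE, pooled over both tissues, therefore reflects mainly the shoot arrays, and the missed call is no evidence against a fall in root. Of the 10 tested genes of ammonium assimilation, 4 fell and 1 rose (5 and 2 when adjusted over the list alone), and the list was shifted down (median -0.27, camera adjusted p = 0.0292, adjusted p = 0.436 with an estimated correlation, 0.038 with the slide block, 0.0356 within the shared slide). Both nitrite reductases fell, NiR2 by 0.79 ± 0.07 (adjusted p = 0.00017) and NiR1 by 0.33 ± 0.08 (adjusted p = 0.0371), while the nitrate reductase NIA1 had a log2 change of 0.03 ± 0.15 (adjusted p = 0.952). The 5 genes of nitrate reduction were shifted down (camera adjusted p = 0.0246, adjusted p = 0.436 with an estimated correlation, 0.00273 with the slide block, 0.00233 within the shared slide), with 2 fallen also when adjusted over the list alone. With the slide block NADH-GOGAT1, GS1;2 and NiR2 kept their calls, while GDH1, GDH2, ASN2 and NiR1 did not (adjusted p = 0.353, 0.175, 0.0842 and 0.218). NIA1 and NIA2 are close copies with uncertain probe signals.

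Regulators that nitrate or ammonium induces in rice or related plants fell together in root. LBD39 fell by 1.81 ± 0.12 and LBD38 by 1.35 ± 0.10 (adjusted p = 4.94e-05 and 0.000105), 2 transcription factors related to repressors of nitrate-responsive genes. The MYB-type factor HHO-like a (Os03g0764600), a relative of the nitrate-induced repressor NIGT1, fell by 1.39 ± 0.09 (adjusted p = 4.94e-05). ACTPK1, a kinase that inactivates AMT1;2 when ammonium is plentiful, fell by 2.36 ± 0.24 (adjusted p = 0.000533). NLP1, of the family of nitrate-responsive NIN-like activators, rose by 0.66 ± 0.10 (adjusted p = 0.00573). Of 12 tested nitrogen regulators, 9 fell and 1 rose, the same numbers as when adjusted over the list alone, and 7 of the 9 falls and the 1 rise kept their calls with the slide block. The list median was -1.19 (camera adjusted p = 6.07e-12, 3.91e-13 with the slide block) and -1.27 within the shared slide (adjusted p = 8.15e-12). This was the 1 list of the root comparison that passed with an estimated correlation (adjusted p = 0.0407).

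Phosphate starvation genes were lower in root after nitrogen was removed, although both groups lacked phosphate. SPX1, a phosphate sensor that restrains the starvation response, fell by 0.94 ± 0.09 (adjusted p = 0.000362), SPX-MFS2 by 1.21 ± 0.10 (adjusted p = 0.000193) and the phosphoenolpyruvate carboxylase kinase PPCK1 by 1.03 ± 0.07 (adjusted p = 6.16e-05). SQD2, which makes sulfolipids that replace phospholipids, fell by 0.56 ± 0.07 (adjusted p = 0.00232), and the phosphate transporter PT6 by 0.85 ± 0.21 (adjusted p = 0.0477, with the slide block 0.421). The non-coding transcript IPS1 had a log2 change of -0.74 ± 0.20 (adjusted p = 0.0739), SPX2 of -0.33 ± 0.13 (adjusted p = 0.202) and PT2 of 0.01 ± 0.11 (adjusted p = 0.98), and these 3 did not pass. Of 19 tested genes, 10 fell and 0 rose (15 fell when adjusted over the list alone), and 4 of the 10 kept their calls with the slide block. Their median was -0.66 (camera adjusted p = 1.26e-14, adjusted p = 0.0887 with an estimated correlation, 2.27e-17 with the slide block) and -0.71 within the shared slide (adjusted p = 8.25e-18). Among genes of phosphate transport and signalling, PHO1;1, PHO1;2 and PHO1;3, of the family that loads phosphate into the xylem, fell by 0.98 ± 0.09, 0.73 ± 0.08 and 1.74 ± 0.18, and the other 8 tested genes did not pass. All 3 kept their calls with the block, and the same 3 passed when adjusted over the list alone. That list was shifted down (median -0.09, camera adjusted p = 0.0215, adjusted p = 0.407 with an estimated correlation, 0.031 with the slide block), but its adjusted p within the shared slide was 0.0506.

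Several other groups shifted in root. Of 12 amino acid transporters, 4 rose (7 when adjusted over the list alone), the cationic amino acid transporter Os03g0654400 by 1.02 ± 0.09 (adjusted p = 0.00017), the permease Os01g0607200 by 0.81 ± 0.08 (adjusted p = 0.000449), Os01g0209800 by 0.60 ± 0.11 and Os07g0134000 by 0.46 ± 0.11, of which the last 2 lost their calls with the slide block (adjusted p = 0.343 and 0.56). The list was shifted up (camera adjusted p = 4.53e-06, adjusted p = 0.194 with an estimated correlation, 5.6e-05 with the slide block, 5.11e-05 within the shared slide). The trehalose-6-phosphate phosphatases Os08g0409100 and Os02g0661100 fell by 1.01 and 0.81 (with the slide block adjusted p = 0.0428 and 0.17), and the 10 genes of trehalose metabolism (4 fallen and 1 risen when adjusted over the list alone) were shifted down (camera adjusted p = 0.006, adjusted p = 0.316 with an estimated correlation, 0.00362 with the slide block, 0.00566 within the shared slide). In the list of the pentose phosphate pathway and root ferredoxin, 8 of 39 fell (1 of these kept its call with the slide block) and 0 rose, against 11 and 1 when adjusted over the list alone (camera adjusted p = 0.000542, adjusted p = 0.208 with an estimated correlation, 8.09e-05 with the slide block, 2.1e-05 within the shared slide). This list was chosen by words for dehydrogenases of the pathway, ferredoxin and uroporphyrin, so it also holds other ferredoxin-linked and tetrapyrrole enzymes. Its shift therefore does not stand for the pentose phosphate pathway. Its leading members were NiR2, the uroporphyrinogen methyltransferase Os01g0631200, which makes the sirohaem of nitrite reductase, with a fall by 0.83 ± 0.11, the ferredoxin-thioredoxin reductase subunit Os04g0528800 with a fall by 0.52 ± 0.06, and the root ferredoxin-NADP reductase Os03g0784700 with a fall by 0.32 ± 0.06. The last 3 lost their calls with the slide block (adjusted p = 0.0685, 0.0778 and 0.275). Of 55 WRKY factors, Os01g0734000, Os01g0665500 and Os02g0265200 rose by 1.19, 0.29 and 0.29, also when adjusted over the list alone, and of 10 autophagy genes Os04g0682000 rose by 0.27 (3 rose when adjusted over the list alone). None of these 4 rises kept its call with the slide block (adjusted p = 0.218, 0.347, 0.263 and 0.456). Both lists were shifted up (camera adjusted p = 0.006 and 0.00195, adjusted p = 0.481 and 0.316 with an estimated correlation, 0.00361 and 0.00634 for the lists with the slide block, 0.00445 and 0.0115 within the shared slide).

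Further lists shifted in root with few changed members. Of 170 cytochromes P450, 13 rose, among them Os02g0503700 by 1.28 ± 0.20 and Os07g0482900 by 1.11 ± 0.16, and Os01g0804200 fell by 0.45 ± 0.10 (15 rose and 4 fell when adjusted over the list alone). Of 71 class III peroxidases, Os03g0234500, Os01g0327100 and Os07g0639400 rose, the last 2 by 0.87 and 0.48, also when adjusted over the list alone. None of these calls in either list was kept with the slide block. Both lists were shifted up (camera adjusted p = 0.006 and 0.0494, adjusted p = 0.316 and 0.604 with an estimated correlation), but not with the slide block (adjusted p = 0.148 and 0.451) or within the shared slide (adjusted p = 0.144 and 0.313). Of 13 TIFY proteins, Os09g0401300 rose by 0.33 ± 0.06 (adjusted p = 0.238 with the slide block, 3 rose and 1 fell when adjusted over the list alone), and the list was shifted up (camera adjusted p = 0.0246, adjusted p = 0.58 with an estimated correlation, 0.0418 with the slide block), but not within the shared slide (adjusted p = 0.0693). The cytosolic ribosomal protein genes were shifted down with a median of -0.14 (camera adjusted p = 1.47e-06, adjusted p = 0.658 with an estimated correlation, 0.000431 with the slide block, 0.00042 within the shared slide), although 0 of 148 fell and Os04g0346100, for ribosomal protein S27, rose by 0.22 (adjusted p = 0.612 with the slide block, 0 of 148 passed when adjusted over the list alone). The light harvesting genes (0 of 12 changed, 4 with an unadjusted p under 0.05) and photosynthesis markers (RbcS4 fell by 0.67 ± 0.13, with the slide block adjusted p = 0.116, the other 7 did not pass) were also shifted down (camera adjusted p = 0.0267 and 0.0445, adjusted p = 0.652 and 0.625 with an estimated correlation, 4.41e-05 and 0.00317 with the slide block, 2.97e-07 and 0.000317 within the shared slide). On single arrays the groups overlapped for both lists, with medians of 0.37, 0.28 and -0.31 on the -P arrays against -0.14, -0.31 and 0.05 on the -P/-N arrays for light harvesting, and of 0.29, 0.38 and -0.28 against -0.15, -0.37 and 0.19 for the markers. In both lists -P replicate 3 stood apart from the other -P arrays, and the values with the block and within the slide rest on -P replicate 1. RbcS2 had a log2 change of -0.72 ± 0.31 in root (adjusted p = 0.25) and RCc3 of 0.11 ± 0.39 (adjusted p = 0.934). Histone genes (0 of 47 changed, 5 with an unadjusted p under 0.05) were shifted down (camera adjusted p = 0.0285, adjusted p = 0.708 with an estimated correlation), but not with the slide block (adjusted p = 0.66) or within the shared slide (adjusted p = 0.56). The remaining 14 lists were not shifted in root, with adjusted p from 0.109 to 0.809. Among these were the cytokinin list (RR6 rose by 0.46 ± 0.09, with the slide block adjusted p = 0.288, the other 11 genes did not pass), the circadian clock (0 of 9 changed), the root markers (0 of 4) and the reference genes (0 of 4), the last 3 lists with 0 genes of an unadjusted p under 0.05.

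Other large changes in root were these. Allantoinase (Os04g0680400), which breaks down ureides, rose by 2.44 ± 0.09 (adjusted p = 8.51e-07), an L-asparaginase (Os04g0650700) by 2.18 ± 0.12 (adjusted p = 2.74e-05) and the protein kinase Os05g0253200 by 2.22 ± 0.31 (adjusted p = 0.00298, with the slide block 0.112). A peroxidase, Os03g0234500, was not well above background in -P and was 4.24-fold above the floor in -P/-N (adjusted p = 0.0016, with the slide block 0.0792). The non-symbiotic hemoglobins Hb2 (Os03g0226200) and Hb1 (Os03g0233900), which take part in nitric oxide turnover, fell by 3.33 ± 0.28 and 2.16 ± 0.22 (adjusted p = 0.00017 and 0.000476). A pyrophosphate-dependent phosphofructokinase, Os05g0194900, fell by 2.54 ± 0.08 (adjusted p = 1.82e-07, with the slide block 1.54e-05). A KAT1-type potassium channel (Os01g0756700) fell by 2.66 ± 0.26, a lectin (Os04g0173800) by 2.42 ± 0.19, an aldolase (Os08g0120600) by 2.42 ± 0.26 and a Bowman-Birk inhibitor (Os03g0823400) by 2.49 ± 0.33 (slide-blocked adjusted p = 0.0293, 0.00909, 0.0465 and 0.0898). The aldolase was well above background on 2 of the 3 -P/-N arrays.

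In total, 1149 of 23602 tested genes changed in root (4.87%, limma, Benjamini-Hochberg adjusted p under 0.05), 591 higher and 558 lower in -P/-N, and 218 of them by at least 2-fold. Fitted on the 6 root arrays alone, 914 genes were higher and 756 lower. Without root -P/-N replicate 3 the numbers were 253 and 312, and without root -P replicate 2 they were 307 and 346. With the slide as a block the count was 196 (66 higher and 130 lower, 109 of them by at least 2-fold), of which 171 were among the 1149, and within the shared slide it was 85 (38 higher and 47 lower, 69 by at least 2-fold). For all 66 root and 80 shoot changes named in the text the 3 arrays of the groups did not overlap. By chance 10% of genes would do so, but the named genes were chosen for passing the test, so this carries no evidence of its own. Of them 32 and 50 kept their calls with the slide block. The naming rule fixed before the files were opened does not cover AMT1;3, AMT2;2, GDH2, NLP1 and Os01g0804200 in root or PHO1;1, AMT3;1, AMT2;1, NLP1, Os12g0524700 and Os05g0565500 in shoot, which were chosen after their values were seen. Of the 33 tested lists, 19 were shifted (8 up and 11 down), 16 with the slide block, 14 within the shared slide and 1 with an estimated correlation. The list medians of the 3 arrays of either group did not overlap for 14 of the 19, and overlapped for nitrate reduction, photosynthesis markers, light harvesting, peroxidases and histones. By chance 10% of lists would be free of overlap, but these lists were chosen for being shifted on the same arrays, so this carries no evidence of its own.

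In shoot, the phosphate starvation genes fell. GDPD2, which breaks down glycerophosphodiesters, fell by 2.44 ± 0.12 (adjusted p = 6.31e-06), SPX1 by 1.42 ± 0.09 (adjusted p = 1.64e-05), SQD2 by 1.05 ± 0.07 (adjusted p = 2.93e-05) and PPCK2 by 0.87 ± 0.07 (adjusted p = 5.17e-05). SPX5 fell by 3.10 ± 0.29 (adjusted p = 0.000135) and was well above background on 1 of the 3 -P/-N arrays. IPS1 fell by 1.04 ± 0.20 (adjusted p = 0.00607) and SPX2 by 0.92 ± 0.13 (adjusted p = 0.00119). PT2, a low-affinity phosphate transporter, rose by 0.40 ± 0.11 (adjusted p = 0.0282, with the slide block 0.468), while PT6 had a log2 change of 0.06 ± 0.21 (adjusted p = 0.864). Of 17 tested genes, 13 fell and 1 rose, as they did when adjusted over the list alone, and 12 of the 13 falls kept their calls with the slide block. As a group they had a median of -0.93 (camera adjusted p = 3.91e-09, adjusted p = 0.293 with an estimated correlation, 1.98e-09 with the slide block) and -0.94 within the shared slide (adjusted p = 1.81e-09). Of the genes of phosphate transport and signalling, SPX-MFS1 rose by 1.53 ± 0.11, PHR1 by 0.23 ± 0.06 and PHO1;1 by 0.31 ± 0.09, PHO2 and PHO1;3 fell by 0.72 ± 0.09 and 1.11 ± 0.18, and the other 8 did not pass (5 rose and 2 fell when adjusted over the list alone). PHR1 and PHO1;1 lost their calls with the slide block (adjusted p = 0.215 and 0.21). That list was not shifted (median 0.12, camera adjusted p = 0.452).

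**Figure D2:**
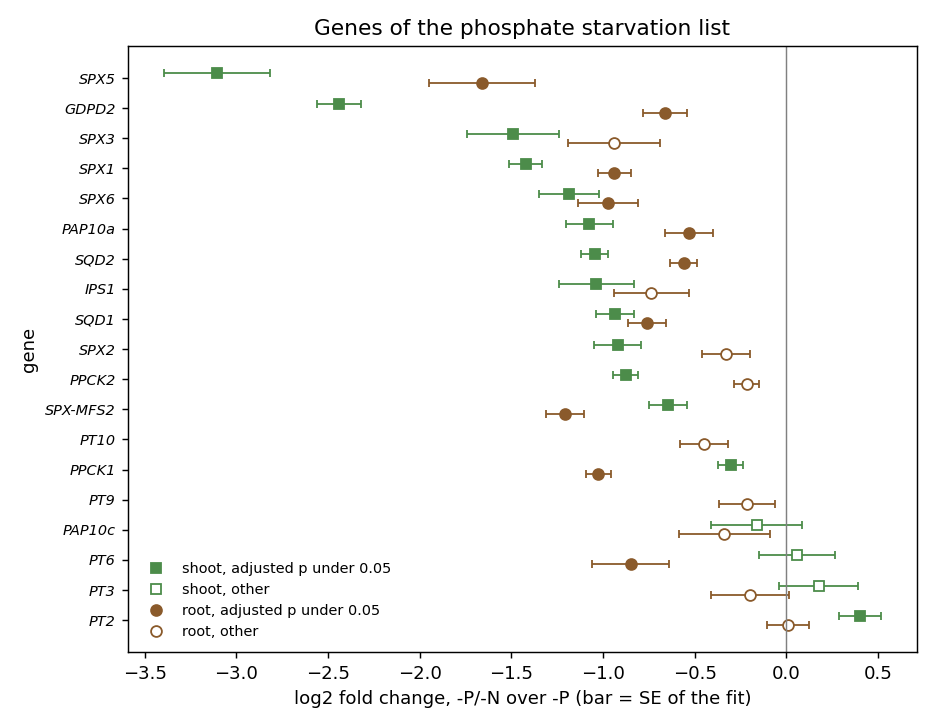
Log2 fold change of -P/-N over -P for the tested genes of the phosphate starvation list in shoot and root, with the SE of the fit; filled symbols passed the test (limma adjusted p under 0.05). In shoot 13 genes fell and 1 rose, and in root 10 fell and 0 rose.

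Nitrogen regulators and cytokinin response genes also fell in shoot. NIGT1 fell by 2.21 ± 0.13 (adjusted p = 1.28e-05), HHO-like a by 1.93 ± 0.09 (adjusted p = 6.31e-06), LBD39 by 1.48 ± 0.12 (adjusted p = 5.18e-05) and HHO3, another relative of NIGT1, by 1.47 ± 0.12 (adjusted p = 5.19e-05). NLP1 rose by 0.66 ± 0.10 (adjusted p = 0.00204). Of 12 tested nitrogen regulators, 8 fell and 1 rose (10 and 1 when adjusted over the list alone), and 5 of the 8 falls and the 1 rise kept their calls with the slide block. The list median was -0.64 (camera adjusted p = 1.51e-05, adjusted p = 0.281 with an estimated correlation, 2.48e-05 with the slide block) and -0.62 within the shared slide (adjusted p = 4.96e-05). Of the 8 tested response regulators of type A, a class that cytokinin induces, 6 fell, among them RR2 by 1.11 ± 0.06 (adjusted p = 9.74e-06), RR6 by 1.27 ± 0.09 (adjusted p = 3.61e-05), RR9 by 1.24 ± 0.10 (adjusted p = 5.5e-05) and RR4 by 0.98 ± 0.08 (adjusted p = 5.84e-05). RR3 and RR11 did not pass (adjusted p = 0.231 and 0.986), and RR1 fell but lost its call with the slide block (adjusted p = 0.222). Of 11 tested genes of cytokinin response and turnover, 7 fell and 0 rose, also when adjusted over the list alone, and 6 of the 7 kept their calls with the slide block. The list median was -0.98 (camera adjusted p = 7.46e-06, adjusted p = 0.281 with an estimated correlation, 2.7e-05 with the slide block) and -1.01 within the shared slide (adjusted p = 9.27e-05).

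Cytosolic ribosomal protein genes fell nearly throughout in shoot, each by a modest amount. Ribosomal protein L32A (Os09g0502000) fell by 0.91 ± 0.09, L36 (Os01g0840700) by 0.83 ± 0.10, L30 (Os01g0812800) by 0.80 ± 0.09 and S29 (Os11g0634500) by 0.66 ± 0.08 (adjusted p = 0.000139, 0.000441, 0.000397 and 0.000634). Of 148 tested genes, 141 fell and 1 rose (145 and 1 when adjusted over the list alone). The gene that rose, Os12g0524700 by 0.50 ± 0.13, is described as a mitochondrial ribosomal protein and lost its call with the slide block (adjusted p = 0.285). The median of these genes was -0.64 (camera adjusted p = 1.01e-38, adjusted p = 0.53 with an estimated correlation, 7.9e-22 with the slide block) and -0.45 within the shared slide (adjusted p = 8.28e-21), and 15 of the 141 falls kept their calls with the block. The list varied between arrays of 1 group, with medians of 0.13, 0.32 and 0.53 on the -P arrays and -0.05, -0.42 and -0.50 on the -P/-N arrays, relative to each gene's mean. Shoot -P/-N replicate 1, the array at -0.05, stood apart from the other 2 arrays of its group over all genes (SD of the log2 difference 0.441 and 0.409, against 0.286 between those 2). The 4 reference genes had a similar profile, with medians of 0.002, 0.191 and 0.367 on the -P arrays and 0.037, -0.286 and -0.28 on the -P/-N arrays. All 4 had negative log2 changes in shoot. Of the 4 reference genes, eEF1a fell by 0.51 ± 0.10 and UBQ5 by 0.56 ± 0.13 in shoot, both also when adjusted over the list alone, but neither with the slide block (adjusted p = 0.114 and 0.222), and this list was not shifted (camera adjusted p = 0.0983).

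**Figure D3:**
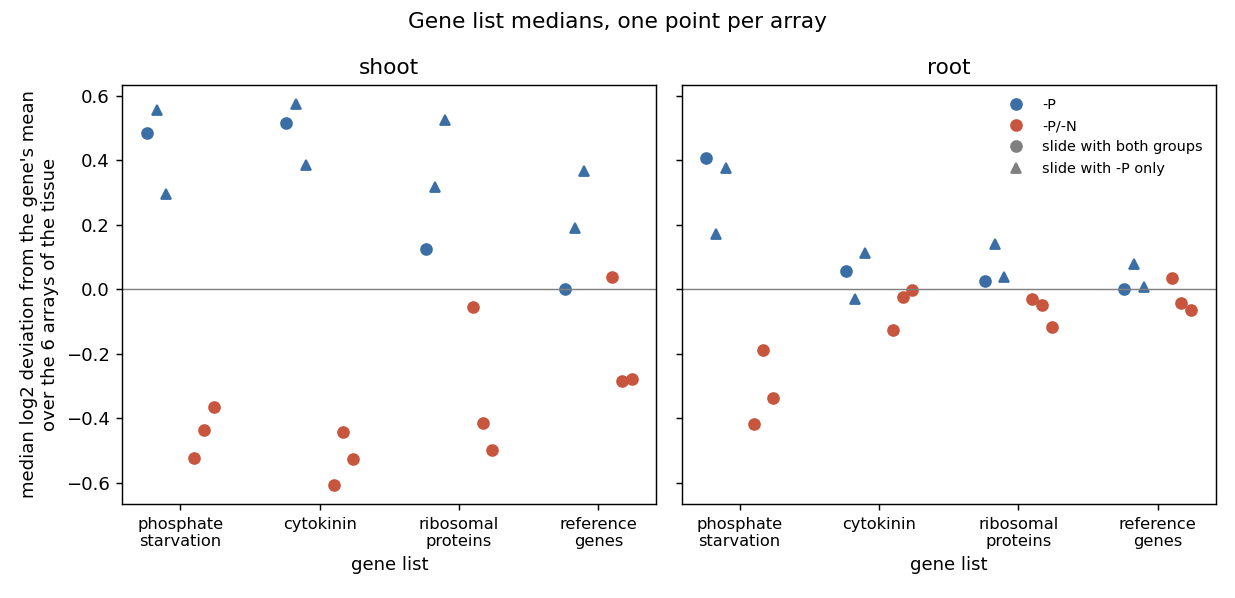
Median level of 4 gene lists on each array, as the log2 deviation from each gene's mean over the 6 arrays of its tissue, with round points for the slide that holds both groups and triangles for the slide with -P only. In shoot the ribosomal protein list lies between 0.13 and 0.53 on the -P arrays and between -0.50 and -0.05 on the -P/-N arrays.

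Nitrogen transport and assimilation genes moved both ways in shoot, and none of these 4 lists was shifted (camera adjusted p = 0.776, 0.372, 0.143 and 0.775 for nitrate transport, ammonium and urea transport, nitrate reduction and ammonium assimilation). NRT1.1B and NRT1.1C rose by 0.57 ± 0.13 and 0.66 ± 0.18, NPF7.2 fell by 1.05 ± 0.22, and the other 6 nitrate transport genes did not pass. NRT2.1 was not well above background on any shoot array and AMT1;2 was so on 2 of the 3 arrays of each group, so neither was tested there. DUR3 rose by 1.66 ± 0.18 (adjusted p = 0.000353), AMT3;3 by 1.14 ± 0.14 (adjusted p = 0.000519), AMT1;1 by 0.83 ± 0.12 (adjusted p = 0.00153) and AMT3;1 by 0.73 ± 0.15, and AMT2;1 fell by 0.31 ± 0.08. AMT2;3 was not well above background in -P/-N, and its level in -P was 7.8-fold above the floor (adjusted p = 2.42e-05, with the slide block 0.00219). NiR2 and NiR1 fell by 0.34 ± 0.07 and 0.32 ± 0.08, while NIA1 had a log2 change of -0.21 ± 0.15 (adjusted p = 0.343). NADH-GOGAT1 and ASN2 rose by 0.41 ± 0.08 and 0.27 ± 0.09, GS1;2 and the plastid enzyme GS2 fell by 0.58 ± 0.11 and 0.41 ± 0.10, and ASN1 had a log2 change of -0.95 ± 0.86 (adjusted p = 0.453). With the slide block NRT1.1C, AMT3;1, AMT2;1, NiR2 and NiR1 lost their calls (adjusted p = 0.17, 0.0756, 0.0962, 0.0587 and 0.222), as did NADH-GOGAT1, ASN2 and GS2 (adjusted p = 0.11, 0.387 and 0.113). The same numbers of genes passed in each of the 4 lists when adjusted over the list alone.

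Iron genes moved both ways in shoot as well. IRO2, a transcription factor of iron uptake, rose by 1.97 ± 0.35 (adjusted p = 0.00393, with the slide block 0.0767), the nicotianamine synthase NAS1 by 1.27 ± 0.25 (adjusted p = 0.00669, with the slide block 0.00393) and the metal transporter NRAMP1 by 1.12 ± 0.19 (adjusted p = 0.00329, with the slide block 0.0666). NAS3 fell by 0.78 ± 0.15, the other 4 tested genes did not pass (3 rose and 2 fell when adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.423). NAS1 has a near-identical copy, NAS2, so its probe signal is uncertain. In the list of the pentose phosphate pathway and root ferredoxin, 9 of 39 fell and 1, the 6-phosphogluconate dehydrogenase Os05g0565500, rose by 0.40 ± 0.12. Of these, 4 falls and not the rise (adjusted p = 0.281) kept their calls with the slide block. The same numbers passed when adjusted over the list alone, and the list was shifted down (median -0.13, camera adjusted p = 0.00168, adjusted p = 0.325 with an estimated correlation, 0.00127 with the slide block, 0.000647 within the shared slide). The members with the lowest adjusted p were the uroporphyrinogen decarboxylase Os03g0337600, of tetrapyrrole synthesis, with a fall by 1.16 ± 0.11, the ferredoxin-thioredoxin reductase subunits Os04g0528800 and Os02g0638300 with falls by 0.48 ± 0.06 and 0.58 ± 0.09, and the methyltransferase Os01g0631200 with a fall by 0.68 ± 0.11. None of these is an enzyme of the pentose phosphate pathway, so the shift of the list does not stand for that pathway. Of 54 WRKY factors 7 rose and WRKY10 (Os01g0186000) fell by 0.94 ± 0.13 (5 and 1 when adjusted over the list alone). Of 10 autophagy genes, Os03g0644000 (Apg6 family), Os02g0117800 (APG5), Os11g0100100 and Os08g0191600 rose by 0.36, 0.33, 0.25 and 0.22 (5 rose when adjusted over the list alone). With the slide block WRKY10 kept its call, while none of the 7 WRKY rises and 4 autophagy rises did. Both lists were shifted up (camera adjusted p = 0.0176 for both, adjusted p = 0.7 for both with an estimated correlation), but not with the slide block (adjusted p = 0.627 and 0.315) or within the shared slide (adjusted p = 0.45 and 0.255), and for the WRKY list the medians of single arrays overlapped between the groups.

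Among the lists that were not shifted in shoot, none of the 8 photosynthesis markers changed (camera adjusted p = 0.452), with a log2 change of -0.03 ± 0.31 for RbcS2 (adjusted p = 0.949), and none of the 9 clock genes changed (3 with an unadjusted p under 0.05, camera adjusted p = 0.918). The 25 lists that were not shifted in shoot had adjusted p from 0.0511 to 0.999, and in 3 of them (nitrate transport, glutathione S-transferases and trehalose metabolism) the median and the mean differed in sign.

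Other large changes in shoot were these. Arginine decarboxylase (Os04g0107600), an entry enzyme of polyamine synthesis, fell by 4.08 ± 0.56 (adjusted p = 0.0011) and was well above background on 1 of the 3 -P/-N arrays. Agmatine coumaroyltransferase (Os04g0664500) was not well above background in -P/-N, and its level in -P was 7.28-fold above the floor (adjusted p = 0.00224). A monogalactosyldiacylglycerol synthase (Os08g0299400) fell by 3.49 ± 0.22 (adjusted p = 1.61e-05), a glutaredoxin (Os01g0368900) by 4.07 ± 0.33 (adjusted p = 5.75e-05), a beta-glucosidase aggregating factor (Os12g0198700) by 3.8 ± 0.27 (adjusted p = 2.85e-05) and the P-type trefoil protein Os06g0121300 by 3.3 ± 0.90 (adjusted p = 0.0242, with the slide block 0.134). The glutaredoxin and the trefoil protein were each well above background on 2 of the 3 -P/-N arrays. Among the rises, an EGF-like domain protein (Os04g0366000) was not well above background in -P and was 3.67-fold above the floor in -P/-N (adjusted p = 5.11e-05, with the slide block 0.00113). An amino acid or polyamine transporter (Os03g0254200) rose by 2.4 ± 0.22 (adjusted p = 0.000124), the defence proteins PR1a (Os07g0129200) and PR-1 (Os01g0382000) by 2.21 ± 0.33 and 2.1 ± 0.39, a terpene synthase (Os02g0121700) by 2.25 ± 0.58, an indole-3-glycerol phosphate synthase (Os09g0255400) by 2.06 ± 0.58, and the kinases Os04g0370900 and Os11g0514400 by 2.3 ± 0.36 and 2.05 ± 0.35. Of these 8 rises, PR1a, the transporter and the EGF-like protein kept their calls with the slide block. Os11g0514400 was well above background on 2 of the 3 -P arrays.

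In total, 5421 of 22275 tested genes changed in shoot (24.3%), 2670 higher and 2751 lower in -P/-N, and 335 of them by at least 2-fold. Without scaling between arrays the median of all genes moved from 0.03 to 0.12 and the split became 3979 higher and 1605 lower, so the directions given are relative to the scaled arrays. With the slide as a block the count was 2246 (1067 higher and 1179 lower, 337 of all genes by at least 2-fold), of which 1801 were among the 5421, and within the shared slide it was 790 (325 higher and 465 lower, 222 by at least 2-fold). Without shoot -P/-N replicate 1, which stood apart, 2703 genes were higher and 2677 lower, 471 by at least 2-fold. Without -P replicate 3, -P/-N replicate 2 or -P/-N replicate 3 the number of higher genes was 1545, 1724 and 1627. Fitted on the 6 shoot arrays alone, 1408 genes were higher and 1844 lower, against 914 and 756 on the 6 root arrays alone. The main fit pooled the spread of both tissues, although shoot replicates differed more (SD of the log2 difference 0.283 to 0.441, against 0.212 to 0.261 in root). The gap between the tissues in the number of changed genes was thus smaller without this pooling. Of the 32 tested lists, 7 were shifted (2 up and 5 down), 5 with the slide block, 5 within the shared slide and 0 with an estimated correlation (4 with an unadjusted p under 0.05). With the shoot arrays split in other ways 2 to 9 lists were called, so the number 7 does not stand out. In both tissues the list tests with the block and within the slide also used the preset correlation, so they are no check on it.

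Root and shoot shared part of their response. Among 20975 genes tested in both tissues, 446 changed in both, against 254 for independent lists, and 383 of them changed in the same direction. Of these, 164 rose in both tissues (63.3 for independent lists, Fisher's exact test, two-sided p = 2.51e-32) and 219 fell in both (63.9, p = 7.9e-68), while 38 and 25 changed in opposite directions (61.6 and 65.6). Genes are not independent replicates, so these p-values describe the overlap across genes. The fit gave each gene the same variance in both tissues, so genes of low variance are called more readily in both. Part of the excess over 254 and the size of these p-values may therefore come from the fit. A shared variance does not set the direction of a change, and 383 of the 446 changed in the same direction. Both tissues had the same slide layout, however, so a slide effect common to both could also give the same direction. Fitted on the 6 arrays of each tissue alone, 327 genes changed in both, with no expected number computed. NLP1, DUR3 and AMT3;3 were among the genes that rose in both tissues, and SPX1, SQD2, LBD39 and GS1;2 among those that fell in both. With the slide as a block 74 genes changed in both tissues, and within the shared slides 21.

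The responses of root and shoot differed for 1472 of the 20975 genes (limma interaction test), 834 with a higher and 638 with a lower response in root, but for 48 with the slide as a block and for 2 within the shared slides. The arginine decarboxylase Os04g0107600 and the beta-glucosidase aggregating factor Os12g0198700 fell in shoot and had log2 changes of 0.10 ± 0.56 and 0.17 ± 0.27 in root (differences of 4.18 ± 0.80 and 3.97 ± 0.38, adjusted p = 0.0172 and 0.000863, with the slide block 0.166 and 0.0347). The first was well above background on 1 of the 3 shoot -P/-N arrays, so the size of its difference is not known exactly. NRT2.3 rose in root and had a log2 change of -0.43 ± 0.30 in shoot (difference 2.78 ± 0.43, adjusted p = 0.007, with the slide block 0.114). The phosphofructokinase Os05g0194900 fell in root and had a log2 change of 0.00 ± 0.08 in shoot (difference -2.53 ± 0.11, adjusted p = 9.85e-06, with the slide block 0.000686). The PR-1 gene Os01g0382000 rose in shoot and had a log2 change of -0.51 ± 0.39 in root (difference -2.61 ± 0.55, adjusted p = 0.025, with the slide block 0.267). It was well above background on 1 of the 3 root -P/-N arrays, so the size of this difference is not known exactly either. NADH-GOGAT1 rose in shoot and fell in root (difference -1.31 ± 0.11, adjusted p = 0.000484, with the slide block 0.0359), as did PHO1;1 (difference -1.29 ± 0.12, adjusted p = 0.000861, with the slide block 0.0504). Of 32 lists tested for a difference, 2 passed, both with a higher response in root. The cytokinin list had a median difference of 0.96 (camera adjusted p = 8.35e-07, adjusted p = 0.463 with an estimated correlation, 8.06e-06 with the slide block) and the ribosomal protein list of 0.52 (camera adjusted p = 1.08e-26, adjusted p = 0.827 with an estimated correlation, 5.47e-13 with the slide block). The phosphate starvation list did not pass this test (median difference 0.30, camera adjusted p = 0.17).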

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

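The comparison of the root and shoot responses was planned, and which genes are listed here was settled only after results were seen, since they are those the text names. Each value was picked out because the interaction test of root against shoot passed, and is the log2 response in root less that in shoot. In all, 1472 genes passed, 48 with the slide as a block, and 51 of the 106 genes named in the text and tested were among them, 6 of these also with the block (RR6, GDPD2, NADH-GOGAT1, Os05g0194900, Os08g0535700 and Os12g0198700). Because the tissues lay on different slides, a slide that altered the response of a gene would enter these differences, and no explanation was tested for them.

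The cytokinin list differed by 0.96 and the cytosolic ribosomal protein list by 0.52, the cytokinin list having fallen in shoot and not shifted in root, and the ribosomal list having shifted down less in root than in shoot. Among the cytokinin genes RR6 differed by 1.73, RR9 by 1.07, RR4 by 0.97 and RR2 by 0.95. Among the ribosomal protein genes Os09g0502000 differed by 0.73, Os01g0812800 by 0.68, Os11g0634500 by 0.44 and Os04g0346100 by 0.36, and the gene described as mitochondrial, Os12g0524700, by -0.81.

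Among genes of nitrogen transport, NRT2.3 differed by 2.78, NPF7.2 by 1.35, AMT2;3 by 1.33, AMT2;1 by 0.63 and AMT1;3 by -0.90. AMT2;3 was not well above background on any shoot -P/-N array, so its difference rests on dim values there and its size is not known. The same holds in part for ACTPK1 and Os04g0107600, above background on 1 of those 3 arrays, and for Os01g0382000 and Os08g0120600, above it on 1 and 2 of the 3 root -P/-N arrays. Among genes of assimilation NADH-GOGAT1 differed by -1.31, NiR2 by -0.45 and GDH1 by -0.34, and among regulators NIGT1 by 0.93, HHO-like a by 0.54, LBD38 by -0.78 and ACTPK1 by -1.69.

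Among phosphate genes GDPD2 differed by 1.78, PPCK2 by 0.66, PHO2 by 0.66, SPX1 by 0.49, SQD2 by 0.49, PPCK1 by -0.72, PHO1;2 by -0.95 and PHO1;1 by -1.29. Of the lipid genes, the phosphodiesterase Os08g0535700 differed by 1.85 and the galactolipid synthase Os08g0299400 by 2.26. Of the iron genes IRO2 differed by -2.25 and NRAMP1 by -1.48.

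The arginine decarboxylase Os04g0107600 differed by 4.18, the aggregating factor Os12g0198700 by 3.97, the cytochrome P450 Os07g0482900 by 1.62, the WRKY factors Os01g0734000 and Os01g0186000 by 1.36 and 0.89, the L-asparaginase Os04g0650700 by 1.16, the uroporphyrinogen decarboxylase Os03g0337600 by 1.14, the allantoinase Os04g0680400 by 0.75 and the permease Os01g0607200 by 0.53. The PR-1 gene Os01g0382000 differed by -2.61, the phosphofructokinase Os05g0194900 by -2.53, the aldolase Os08g0120600 by -2.33, PR1a (Os07g0129200) by -2.09, Hb2 (Os03g0226200) by -2.02, Hb1 (Os03g0233900) by -1.18, the phosphatase Os08g0409100 by -1, proline dehydrogenase (Os10g0550900) by -0.90 and the autophagy gene Os02g0117800 by -0.38.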

How the results depend on the processing

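All alternatives for these results were fixed before the data were examined. The lists noticed in the data, the list tests on the interaction and the named genes outside the naming rule were chosen after seeing the data. So were some predictions and margins for technical explanations, as said below. The text names 213 results for single genes, 197 of them past the threshold, and 0 of the 197 turned direction under any setting. For the 66 root and 80 shoot changes among them the groups' arrays did not overlap. Leaving out arrays, the slide block and the shared slide could therefore not turn these, and testing every probe used the same probe for a named gene. The lack of turns under these settings is thus no evidence of robustness. Over 5896 refits of these results, 5086 kept their direction and side of the threshold, 777 no longer passed, 8 newly passed and 25 turned direction, all among values that had not passed. The number of arrays and the signal over background limit the precision. The cause of the shifts below was not tested, except that leaving out arrays or adding a block leaves fewer degrees of freedom and that testing every probe adds items.

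With the slide as a fixed block the counts were 1067 higher and 1179 lower in shoot, 66 higher, 130 lower and 109 at least 2-fold in root, 74 in both tissues and 48 in the interaction. With only the slide that holds both groups they were 325, 465 and 222 at least 2-fold in shoot, 38, 47 and 69 in root, 21 in both and 2 in the interaction. With a replicate block they were 893 and 1274 in shoot, 129, 158 and 142 in root, 92 in both and 2 in the interaction. The correlations between -P and -P/-N arrays of the same number were -0.522, -0.116 and -0.294 in shoot and -0.201, -0.141 and -0.092 in root. Between shoot and root arrays of the same treatment and number they were -0.04 to 0.143. These values show no pairing of the samples, but with 3 arrays per group they cannot exclude it. With array quality weights 1324 genes were higher and 1166 lower in root, 938 changed in both tissues and 3213 in the interaction. With every probe as its own item 4431 were lower in shoot, 858 lower in root, 714 changed in both and 2215 in the interaction, and 12 lists were shifted in shoot. Without scaling 1605 were lower in shoot and 927 passed the interaction. With normexp 211 changed at least 2-fold in shoot and 134 in root, and with the 6 arrays of the tissue alone 1408 were higher in shoot and 914 in root. Estimating the correlation left 0 lists in shoot and 1 in root, where fry left 12.

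Leaving out each array in turn gave 1545 to 2703 genes higher and 1988 to 2723 lower in shoot, 253 to 642 higher and 303 to 592 lower in root, 289 to 471 at least 2-fold in shoot and 174 to 225 in root, 238 to 463 in both tissues, 690 to 1902 in the interaction, and 6 to 10 lists in shoot and 13 to 19 in root. Omitting 1 array moved a count by more than 1.5 times for genes higher in shoot without -P replicate 3 or -P/-N replicate 2 or 3, for both root counts without any root array but -P replicate 1, for genes in both tissues without any root array, and for the interaction without any root array, shoot -P replicate 3 or shoot -P/-N replicate 2 or 3.

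The values that turned direction had not passed the test. Leaving out each array gave -1.738 to 0.312 for ASN1 in shoot, -0.083 to 0.096 for NIA1 in root, -0.047 to 0.087 for PT2 in root, -0.025 to 0.157 for PT6 in shoot, -0.062 to 0.016 for RbcS2 in shoot, -0.046 to 0.079 for Os05g0194900 in shoot, -0.069 to 0.197 for Os04g0107600 in root and -0.014 to 0.266 for Os12g0198700 in root. With array weights NIA1 and PT2 in root were -0.028 and -0.025 and Os05g0194900 in shoot 0.062. NIA1 in root was -0.096 with the slide block and with only the shared slide. PT2 in root was -0.012 with median scaling and -0.011 with normexp. Without scaling RbcS2 and Os05g0194900 in shoot were 0.053 and 0.084, RbcS2 was 0.067 with quantile normalization, and Os05g0194900 was 0.000 with the authors' values. For all of these the cause was not tested.

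The 6 arrays of a tissue split into 3 against 3 in 10 ways, too few for a p of their own. In shoot the real split gave 2670 higher and 2751 lower genes against at most 464 in either direction in another, and 335 at least 2-fold against 148, while 3 of the 10 splits had 7 or more shifted lists (highest other 9). In root the real split had the highest count in each case (1 of 10), against at most 1 gene in either direction, 1 at least 2-fold and 13 lists. For genes changed in both tissues 1 of 100 pairs of splits reached the real count (highest other 25), and for the interaction 3 of 100 drawn pairs did (highest other 1925, a pair that keeps the real shoot split).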

Other observations

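The lists of this part and the tests on them were chosen only after results were seen, and their p-values are adjusted over these lists alone. Since the same arrays prompted the lists, these p-values describe them and are no independent support. The precursors of the microRNA miR399, which phosphate shortage induces and which targets the transcript of PHO2, fell in shoot. Of 33 items on the array 5 were tested in shoot, the others not being above background often enough in either group. All 5 passed the test, with a median of -2.60 (camera adjusted p = 2.31e-07, adjusted p = 0.0104 with an estimated correlation, 6.4e-07 with the slide block). The items are the ends of single precursors, which the array measures apart, so they are fewer than 5 independent genes. In root 1 item was tested and it did not pass. The precursors of miR169, a family that targets NF-YA factors, had 48 items on the array. In shoot 6 of the 10 tested fell (5 fell and 1 rose with the slide block, median -1.21, camera adjusted p = 0.000312, adjusted p = 0.108 with an estimated correlation). In root 1 of 16 fell (0 with the slide block, median -0.54, camera adjusted p = 5.88e-05, adjusted p = 0.185 with an estimated correlation, 0.00209 with the slide block). Genes of galactolipid synthesis and phospholipid breakdown fell for 9 of 27 and rose for 1 of 27 in shoot (6 and 0 with the slide block, camera adjusted p = 0.00294, adjusted p = 0.108 with an estimated correlation), among them the glycerophosphodiester phosphodiesterase Os08g0535700 by 2.02, while DGD2 (Os03g0268300) rose by 0.41. In root 3 of 28 fell, 0 with the slide block, and the list was not shifted (camera adjusted p = 0.451). Purple acid phosphatases fell for 4 of 9 in shoot (3 with the slide block, camera adjusted p = 0.0017, adjusted p = 0.135 with an estimated correlation) and for 3 of 12 in root (1 with the slide block, camera adjusted p = 0.0866).

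Genes of ureide and amino acid breakdown moved both ways. In shoot 6 of 10 rose and 1 fell (5 and 0 with the slide block, camera adjusted p = 0.0017, adjusted p = 0.0293 with an estimated correlation, 0.00136 with the slide block), and in root 4 of 11 rose and 3 fell (3 and 0 with the slide block, camera adjusted p = 0.00569, adjusted p = 0.0523 with an estimated correlation, 0.00209 with the slide block). Proline dehydrogenase (Os10g0550900) rose by 1.73 in shoot and 0.84 in root, and the L-asparaginase Os04g0650700 rose by 1.02 in shoot as well. The allantoin permease Os12g0502800 rose by 0.39 in shoot and 0.62 in root, while its neighbour Os12g0503000 fell by 1.67 and 1.64. The falls of Os12g0503000 and the root rise of proline dehydrogenase lost their calls with the slide block. Hemoglobin genes fell for 3 of 4 in root, with a median of -1.72 (camera adjusted p = 1.89e-05, adjusted p = 0.0523 with an estimated correlation, 1.1e-09 with the slide block), and Hb2 (Os03g0226200) and Hb1 (Os03g0233900) fell in shoot by 1.32 and 0.98, the first not with the slide block. Hb2 and Hb1 were already named among the large falls in root, so the p-values of this list carry no evidence of their own. Pathogenesis-related proteins and chitinases were not shifted as a group in shoot (8 of 75 rose, 9 fell, camera adjusted p = 0.646) or in root (1 of 80 rose, 5 fell, camera adjusted p = 0.911).

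Technical explanations were weighed for 3 patterns, and for the first, the phosphate starvation genes that fell without nitrogen, the predictions on slides and on single arrays were written after related values had been seen. The list median was -0.94 in shoot and -0.712 in root within the slide that holds both groups. A slide difference as the whole cause would leave little there, but 1 -P array decides this in each tissue, so it could not be excluded. With normexp background correction or quantile normalization the weaker median, less that of all genes, was -0.901 in shoot and -0.649 in root, and over all arrays left out in turn the weakest was -0.887 and -0.619, so neither the background nor 1 array was the whole cause. A biological explanation, that nitrogen supply could tune the phosphate response, remains open, since no group with phosphate was measured here to test it.

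The second pattern is the drop in calls when the slide is a block, in shoot from 5421 to 2246 and in root from 1149 to 196. If a slide effect were its whole cause, the held-out -P replicate 1 would lie near -P/-N, with which it shares a slide, at 1 on a scale on which the other -P arrays lie at 0. Over the genes called without it, its median position was 0.213 in shoot and 0.163 in root, nearer to -P but farther from it than the other -P arrays held out in turn (0.141 and -0.033 in shoot, 0.023 and 0.11 in root), and 1 array excludes nothing, so a slide effect may still contribute. Lower power of the blocked fit may account for the drop in shoot, since the larger of 2 counts with made-up slides was 2239, but in root the 2 counts were 212 and 817 and the test cannot tell. The margins for these verdicts were set after the values were seen, and the prediction on the held-out array made no allowance for resting on 1 array.

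The third pattern is the fall of cytosolic ribosomal protein genes in shoot, for which all 3 predictions were written after the list had been seen. Within the shared slide the median was -0.452, but this rests on 1 -P array, at 0.126 against -0.054, -0.416 and -0.498 on the -P/-N arrays, so a slide difference could not be excluded. The lowest median of 10000 random lists matched on mean level in 20 bins was -0.103, against -0.64 for these genes. They thus fell by more than other genes of the same level bins. Brightness within a bin was not matched, so an effect confined to the brightest probes could not be excluded. Variation between arrays that these genes share could still contribute and was not tested. The exact permutation p of the list mean, 0.1, is the smallest that 3 against 3 arrays can give and says nothing either way. The reference genes had a similar profile over the shoot arrays. Variation shared beyond the ribosomal genes would give this, but so would a fall of both lists, so it does not decide. No biological explanation was tested.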
